A study of Mus musculus with 14 samples.

How the data were processed

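The series holds 14 RNA libraries from primary mouse cell lines, started from embryos at E13.5, as the labels give them. According to the labels the head was used for neurosphere lines, and the body without internal organs for MEF lines. Libraries were made with the QuantSeq 3′ mRNA kit in its forward version, which reads the 3′ ends of polyadenylated transcripts in the sense direction. Samples were grouped by the labels' cell type and genotype: 3 WT and 5 KO MEF lines, 3 WT and 3 KO neurosphere lines, each an independent line. Replicate numbers were not used to pair lines, since the labels state no pairing.

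The deposited files hold expected counts per transcript, made by the authors with Salmon 1.1.0, and TPM, abundances scaled by transcript length and depth, from the same Salmon run; the submitters' processing notes also name edgeR, without a version. Transcript set, genome build, trimming and mapping options are not given in the sources used here. The transcript identifiers were matched to the GENCODE M21 annotation of mouse genome GRCm38, from which the coordinates come: of 116945 transcripts per file, 115560 matched with their version and length and 385 by identifier alone. The 1000 transcripts without a match held 0.251% to 0.425% of the reads and were left out. The expected counts were summed per gene, giving 35449 genes, and rounded. Library totals after this ran from 1669406 to 3296178 counts. A count of 0 was read as up to 3 counts, and where a group had no counts, the fold was computed against 3 counts over its libraries. Floors cover counting error only, since PCR copies cannot be told apart in these files, while the 95% intervals were derived from the edgeR test and include variation between lines.

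Each KO against WT comparison was fitted apart with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the default filter on low counts by group, the robust quasi-likelihood test and the Benjamini-Hochberg adjusted p, with 0.05 as threshold and no fold minimum. The same test was applied to the genotype by cell type interaction over all 14 libraries and to WT neurospheres against WT MEFs. CPM values are scaled by the TMM factors of the comparison in which they are given, means carry the SD over lines, and log2 values come from the edgeR fit. For H3f3a and H3f3b, exact two-sided permutation tests of log2 CPM were added. The default filter kept 10785 genes in MEFs, 10624 in neurospheres, 12113 for the interaction and 11080 for the WT lines.

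For the KO comparisons 37 gene lists, written before the data were examined, were tested with limma 3.58.1: camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and beside it camera with an estimated correlation and fry. Lists with fewer than 5 measured members were not tested. For each list the members were also adjusted over the list alone.

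The rule for named genes was fixed before the data were examined. For each KO comparison it names H3f3a and H3f3b, up to 8 passing genes each way by size, up to 4 passing members of each list and, where fewer than 10 genes pass, the 10 genes with the smallest unadjusted p and a mean of at least 5 CPM in the higher group. Predicted genes count, but are named only among the 3 smallest p. For the interaction it names the 8 genes with the smallest p, and for the WT lines the 5 largest differences each way with a mean of at least 50 CPM, and list members. Further list members that did not pass, genes called by an alternative setting and the genes shown by line were named after their values were seen.

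The tests were checked on simulated counts, drawn from the fitted means and dispersions of the measured genes, with changes put into 200 genes. Only genes above a minimum mean CPM were changed. Each gene was drawn independently, so differences between lines that many genes share were not simulated. The percentages found may therefore be too high for the real lines. Of genes changed 4-fold, 86.6% were found with the MEF design, 65.7% with the neurosphere design and 37.3% with the interaction. Of genes changed 2-fold, 25.4%, 13.4% and 2.99% were found, so changes of this size were mostly not detectable with this number of lines and this depth.

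Alternatives covered DESeq2 1.42.0, size factors in place of TMM, no filter and a stricter filter, the deposited TPM in limma, voom with sample weights, all libraries in 1 fit, a block on replicate number, an FDR of 0.1, genes within 10 Mb of H3f3a left out, and each library left out in turn. Added after the data were seen were covariates for sex (Ddx3y) and for the first residual component, and fits without the lines that stand apart. Xist was planned as the sex covariate, but is not listed in the files. Processed copies of H3f3a were planned to be summed with it, but the 3 such genes listed had 0 counts, so that nothing changed. Principal components were computed on log2 CPM of the tested genes of each cell type. Figures were drawn from the same values. Results that need genes withheld for evaluation are not reported here.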

Results

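Transcript 3′ ends were counted in 14 primary mouse cell lines, all started from embryos at E13.5. The lines were wild type (WT) or carried the targeted H3f3a allele (KO), which the series title calls knockout-first. Such alleles usually hold a gene-trap cassette that is meant to end the transcript early. Body tissue gave embryonic fibroblasts (MEFs), connective tissue cells, and heads gave neurospheres, cultures of neural stem and precursor cells. There were 3 WT and 5 KO MEF lines and 3 WT and 3 KO neurosphere lines, and each line gave 1 library. Counts assigned to genes ran from 2080798 (KO MEFs 3) to 3296178 (WT MEFs 3) in MEFs and from 1669406 (KO neurospheres 2) to 2874677 (WT neurospheres 3) in neurospheres. Group means were 2898382 counts in WT MEFs, 2741015 in KO MEFs, 2481442 in WT neurospheres and 2265476 in KO neurospheres. Mitochondrially encoded transcripts took 5.84% ± 0.270 of counts in WT MEFs and 5.59% ± 0.204 in KO MEFs, and 14.5% ± 2.04 and 15.1% ± 1.15 in WT and KO neurospheres (SD over lines).

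The MEF comparison asked how transcript levels in fibroblasts differ when H3f3a is targeted. H3f3a and its paralog H3f3b encode the same protein, the histone variant H3.3, which is placed into chromatin outside DNA replication. H3f3a transcripts fell from 1031 ± 335 counts scaled to library size (CPM; SD, n = 3 lines) in WT MEFs to 15.1 ± 4.69 CPM (n = 5) in KO MEFs, a 68.3-fold decrease that left 1.46% of the WT level. All 5 KO lines, at 7.16 to 18.6 CPM, lay below the 3 WT lines, at 833 to 1417 CPM. H3f3b stood at 1506 ± 327 CPM in WT and 1484 ± 420 CPM in KO MEFs, so that H3f3a supplied 40.3% ± 3.10 of the H3.3-coding counts in WT MEFs and 1.01% ± 0.258 in KO MEFs. The 2 genes together gave 2537 ± 654 CPM in WT and 1499 ± 423 CPM in KO MEFs, 59.1% of the WT sum (exact two-sided permutation p = 0.0536). By the edgeR quasi-likelihood test the log2 change of H3f3a was -6.09 (SE 0.32, 95% interval -6.82 to -5.36, adjusted p = 0.000115), and the exact two-sided permutation p was 0.0179, the smallest that 3 against 5 lines can give. The log2 value of H3f3b was -0.02 (SE 0.23, 95% interval -0.54 to 0.50, adjusted p = 1.00; exact permutation p = 0.893), and it turned positive, between 0.01 and 0.16, when WT MEFs 2, KO MEFs 1, KO MEFs 4 or KO MEFs 5 was left out.

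H3f3a (ENSMUSG00000060743.12) lies on the minus strand of chromosome 1 from 180800832 to 180813943, and H3f3b (ENSMUSG00000016559.14) on the minus strand of chromosome 11 from 116021912 to 116027962. In WT MEFs 83.3% of H3f3a reads were assigned to the transcript H3f3a-205 and 16.6% to H3f3a-201. In KO MEFs these shares were 68.9% and 30.5%, and in WT and KO neurospheres H3f3a-205 held 90.9% and 92.2%. The KO MEF shares rest on 139.9 and 61.8 estimated reads over all KO MEF lines, against 7419 and 1481 in WT MEFs. The last exons of both transcripts overlap, so the split between them is itself an estimate, and its difference between genotypes was not tested. The last of the 4 exons of H3f3a-205, from 180800832 to 180803205, contains the stop codon and the 3′ untranslated region. Tags from this end count transcripts that reach it. The sources used here do not give the position of the cassette, transcripts that end upstream were not measured, and the H3.3 protein was not measured.

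**Figure D1:**
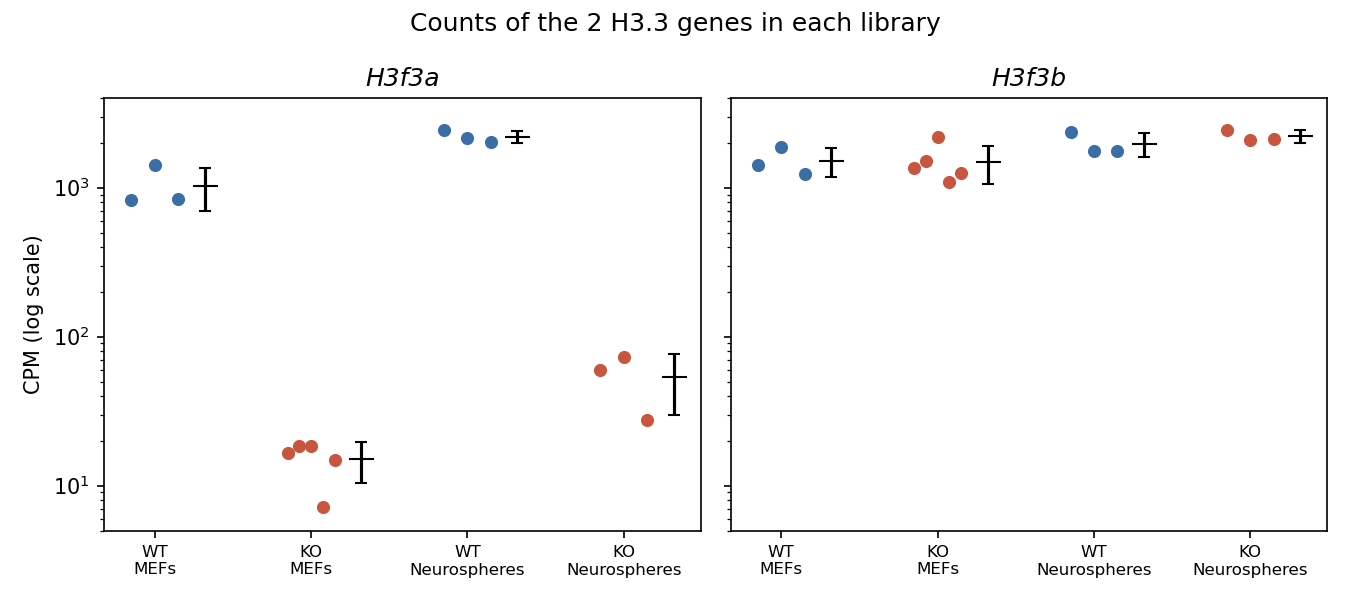
H3f3a and H3f3b in each of the 14 lines, in CPM scaled within each cell type on a log axis; points are single lines, horizontal lines are group means and error bars the SD over lines. H3f3a is at 7.16 to 73.5 CPM in the KO lines and at 833 to 2423 CPM in the WT lines, while H3f3b ranges from 1100 to 2453 CPM over all lines.

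Apart from H3f3a, no gene passed the test in MEFs, so the genes that follow are given as values. Srebf2, which encodes the transcription factor that drives cholesterol synthesis, stood at 109.5 ± 14.3 CPM in WT and 149.6 ± 11.1 CPM in KO MEFs (log2 0.45, SE 0.13). Gnai1, an inhibitory G protein alpha subunit, stood at 15.2 ± 4.15 and 27.1 ± 2.13 CPM (0.83), and Ildr2 at 10.1 ± 0.667 and 20.2 ± 4.06 CPM (1.00). Lower means in KO MEFs were seen for Jcad, a component of endothelial cell junctions (68.1 ± 4.69 to 47.8 ± 3.05 CPM, log2 -0.51), for the ubiquitin ligase gene Trim41 (30.3 ± 2.81 to 18.1 ± 2.96 CPM, -0.74) and for the retinol dehydrogenase gene Rdh5 (10.6 ± 0.767 to 5.30 ± 1.04 CPM). The predicted gene 2300009A05Rik went from 20.7 ± 1.56 to 10.9 ± 1.61 CPM (-0.92), and the pseudogene Gm12346, which lies within Ssh2 on the same strand, from 161 ± 8.04 to 296 ± 73.1 CPM (0.88). In each of these 8 genes all 5 KO lines lay on the same side of all 3 WT lines. By edgeR 1 of 10785 genes, H3f3a, passed at an adjusted p under 0.05. The unadjusted p was under 0.05 for 175 genes, with 539 expected by chance, and DESeq2 called 1 gene, H3f3a, with 212 genes at an unadjusted p under 0.05. A count below chance does not show that KO effects are absent, since it moved with the lines in the fit. By edgeR it ran from 119 (without KO MEFs 4) to 463 (without KO MEFs 3). With the first residual component as covariate, added after the data were seen, it was 693. In 204 genes (1.89%) the KO and WT lines did not overlap, against 3.57% by chance. With WT MEFs 2 and KO MEFs 3 left out, a choice made after the data were seen, 3 genes passed: H3f3a, Ak6 and Gm48499. Ak6, an adenylate kinase gene, had 239.7, 37.2 and 165.7 CPM in WT MEFs 1 to 3 and 27.5 to 66.5 CPM in the 5 KO lines. Taf9, which shares its 3′ end with a transcript of Ak6 on the same strand, stood the other way, at 106.8 ± 53.4 CPM in WT and 212.3 ± 29.8 CPM in KO MEFs (log2 0.99, edgeR adjusted p = 1.00). Taf9 was lowest in WT MEFs 1 (46.5 CPM), the line with the most Ak6. In WT neurospheres Taf9 had 0 counts beside Ak6 at 156.0 ± 3.07 CPM. The Ak6 values may thus reflect how reads were divided between these 2 genes, which was not tested, and do not by themselves show a lower level.

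Of the 37 gene lists fixed before the data were examined, 29 had enough measured members to test in MEFs, and limma camera with a preset correlation called 2 of them lower in KO MEFs. These were the markers of macrophages, microglia and blood (adjusted p = 1.27e-07) and the interferon-stimulated genes (4.67e-07), and both had an adjusted p = 0.654 with an estimated correlation. By fry 0 lists were called, with a smallest adjusted p of 0.559 in either direction. Other splits of the MEF lines into groups of the same sizes gave a median of 5 lists by camera with the preset correlation. All 11 measured markers of macrophages, microglia and blood had negative log2 values, with a median of -1.13. They include the complement gene C1qa (5.85 ± 1.24 CPM in WT, 1.82 ± 1.73 CPM in KO), the myeloid adaptor gene Tyrobp (6.32 ± 5.51 and 1.88 ± 1.39 CPM) and the lysozyme gene Lyz2 (57.9 ± 35.1 and 26.2 ± 18.8 CPM). Of 23 interferon-stimulated genes, which cells switch on against viruses, 21 had negative values, with a median of -0.72. Ifit1 stood at 15.7 ± 21.1 CPM in WT and 2.44 ± 1.87 CPM in KO MEFs, Rtp4 at 18.6 ± 25.1 and 4.12 ± 1.93 CPM, and Lgals3bp at 36.3 ± 24.0 and 16.3 ± 6.33 CPM. No member of either list passed alone, over all genes or adjusted over the list alone.

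WT MEFs 2 had the highest mean of both lists. The mean log2 deviation of the interferon-stimulated genes was 1.37 in WT MEFs 2, against -0.23 and 0.10 in WT MEFs 1 and 3, and from -0.86 to 0.34 in the KO lines. The interferon call ended without WT MEFs 2 (adjusted p = 0.375) and with both WT MEFs 2 and KO MEFs 3 left out (adjusted p = 0.341). The mean deviation of the blood cell markers was 0.29, 1.40 and 0.54 in WT MEFs 1 to 3 and 0.33, 0.88, -1.22, -1.52 and -0.70 in KO MEFs 1 to 5. Their camera call held without WT MEFs 2 (adjusted p = 0.00151), with both WT MEFs 2 and KO MEFs 3 left out (0.0333) and when any other line was left out. The number of lists called was 6 without WT MEFs 1, 5 without WT MEFs 2, 5 without WT MEFs 3 and 4 without KO MEFs 3.

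No other list was called with all MEF lines in the fit without a block. With replicate number as a block, the S phase genes (camera adjusted p = 0.0145) and the G2 and M phase genes (1.50e-09) were called higher. The p53 target genes were then called lower (0.0145). Cholesterol synthesis genes had 20 of 25 members with positive values (median log2 0.17, camera adjusted p = 0.0649), neuron markers 6 of 8 (median 0.38, 0.137) and G2 and M phase genes 34 of 42 (median 0.10, 0.180). With an estimated correlation the cholesterol list and the G2 and M phase list each had a camera adjusted p of 0.862. The estimated correlations were 0.608 for the cholesterol list, 0.736 for G2 and M phase, 0.477 for S phase and 0.887 for ribosomal protein genes. Camera p-values of these lists at the preset 0.01 are therefore too small, and fits without a line were run only with the preset. With the preset correlation, leaving out 1 line changed some of these outcomes. The cholesterol list was called higher without WT MEFs 3 (camera adjusted p = 0.000218), KO MEFs 2 (0.00514) or KO MEFs 3 (0.000142). The G2 and M phase list was called higher without WT MEFs 2 (1.62e-07), KO MEFs 1 (0.0194), KO MEFs 4 (0.00172) or KO MEFs 5 (0.0110), and with both WT MEFs 2 and KO MEFs 3 left out (0.00120). S phase genes were called higher without WT MEFs 2 (camera adjusted p = 0.000547). Ribosomal protein genes were called higher without WT MEFs 1 (0.00104), WT MEFs 3 (2.12e-06) or KO MEFs 3 (0.000141), but lower without WT MEFs 2 (8.30e-06). Of the chromatin lists, the H3 chaperones had 11 of 17 members with positive values (median 0.07, camera adjusted p = 0.420), the H3 lysine methylation enzymes 16 of 29 (median 0.03, 0.755) and the histone variants with polyadenylated transcripts 6 of 12 (median -0.05, 0.540). Neighbours of H3f3a on chromosome 1 had 9 of 20 (median -0.02, 0.755). Among cell type markers, the fibroblast and mesenchyme list had 9 of 15 members with positive values (median 0.10, camera adjusted p = 0.755). Over all genes and adjusted over the list alone, H3f3a was the 1 list member called in MEFs. Median, mean and test differed in sign for the neighbours of H3f3a, the senescence genes, the immediate early genes and the neural stem markers. None of these was called with all lines, and the immediate early genes were called higher without WT MEFs 1 (camera adjusted p = 0.0253).

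The neurosphere comparison asked the same of neural stem and precursor cells. H3f3a transcripts fell from 2197 ± 204 CPM (n = 3) in WT to 53.5 ± 23.5 CPM (n = 3) in KO neurospheres, a 41.3-fold decrease that left 2.43% of the WT level. The 3 KO lines had 27.5 to 73.5 CPM and the 3 WT lines 2024 to 2423 CPM. H3f3b stood at 1965 ± 351 CPM in WT and 2212 ± 209 CPM in KO neurospheres, and H3f3a supplied 52.97% ± 2.18 of the H3.3-coding counts in WT and 2.36% ± 1.07 in KO lines. The summed H3.3-coding counts were 4162 ± 550 CPM in WT and 2266 ± 213 CPM in KO neurospheres, 54.4% of the WT sum. The edgeR log2 change of H3f3a was -5.37 (SE 0.41, 95% interval -6.31 to -4.42, adjusted p = 0.00754). The log2 value of H3f3b was 0.17 (SE 0.24, 95% interval -0.37 to 0.71, adjusted p = 0.999; exact permutation p = 0.3). Exact two-sided permutation p was 0.1 both for H3f3a and for the sum, the smallest that 3 against 3 lines can give. Without WT neurospheres 2 the adjusted p of H3f3a was 0.0801 (log2 -5.38), and without KO neurospheres 1 it was 0.202 (log2 -5.46).

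Apart from H3f3a, no gene passed the edgeR test with the default filter in neurospheres. The gene nearest to passing was Nrn1, which encodes neuritin, a small protein that promotes the growth of neurites. It stood at 0.961 ± 0.960 CPM in WT and 30.2 ± 3.49 CPM in KO neurospheres (log2 4.92, SE 0.67, adjusted p = 0.317). With no filter on low counts edgeR called Nrn1 beside H3f3a. Prrt2, a gene for a synaptic protein, had 0 counts in all WT lines and 6.24 ± 2.70 CPM in KO lines, at least 15.4-fold higher against a floor of 3 counts over the WT group; Gm42742 overlaps it on the same strand. Lower means in KO lines were seen for Fras1, a basement membrane protein gene (47.3 ± 44.5 to 2.54 ± 1.67 CPM, log2 -4.11), for Pcdhga3, a protocadherin that shares its last exons with its gene cluster (41.9 ± 25.5 to 4.47 ± 2.85 CPM, -3.16), and for Tusc1 (10.995 ± 6.79 to 0.506 ± 0.556 CPM, -4.13). The same held for the sodium channel family gene Scn7a (15.8 ± 7.32 to 2.97 ± 0.423 CPM, -2.39), the ubiquitin ligase component Fbxl7 (12.2 ± 5.90 to 1.76 ± 0.874 CPM, -2.76) and Pdcd4, an inhibitor of translation initiation (305 ± 30.4 to 143 ± 35.5 CPM, -1.09). Adjusted p was 0.999 for each of these except Nrn1, and their KO and WT lines did not overlap.

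By edgeR 1 of 10624 genes, H3f3a, passed in neurospheres, with 227 genes at an unadjusted p under 0.05 and 531 expected by chance. Leaving out 1 line, the count at an unadjusted p under 0.05 ran from 185 (without KO neurospheres 2) to 668 (without KO neurospheres 3). A count below chance therefore does not show that KO effects are absent. KO and WT lines did not overlap in 756 genes (7.12%), against 10% by chance. DESeq2 called 5 genes: H3f3a, Nrn1 (adjusted p = 1.14e-07), Fras1 (0.000644), Pcdhga3 (0.00177) and Gm42742. The edgeR count was 0 without WT neurospheres 2 or KO neurospheres 1, and 2 without WT neurospheres 1, H3f3a and Gm15500. With WT neurospheres 2 and KO neurospheres 3 left out, a choice made after the data were seen, it was 3: H3f3a, Gpr37l1 and Pcdh15.

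**Figure D2:**
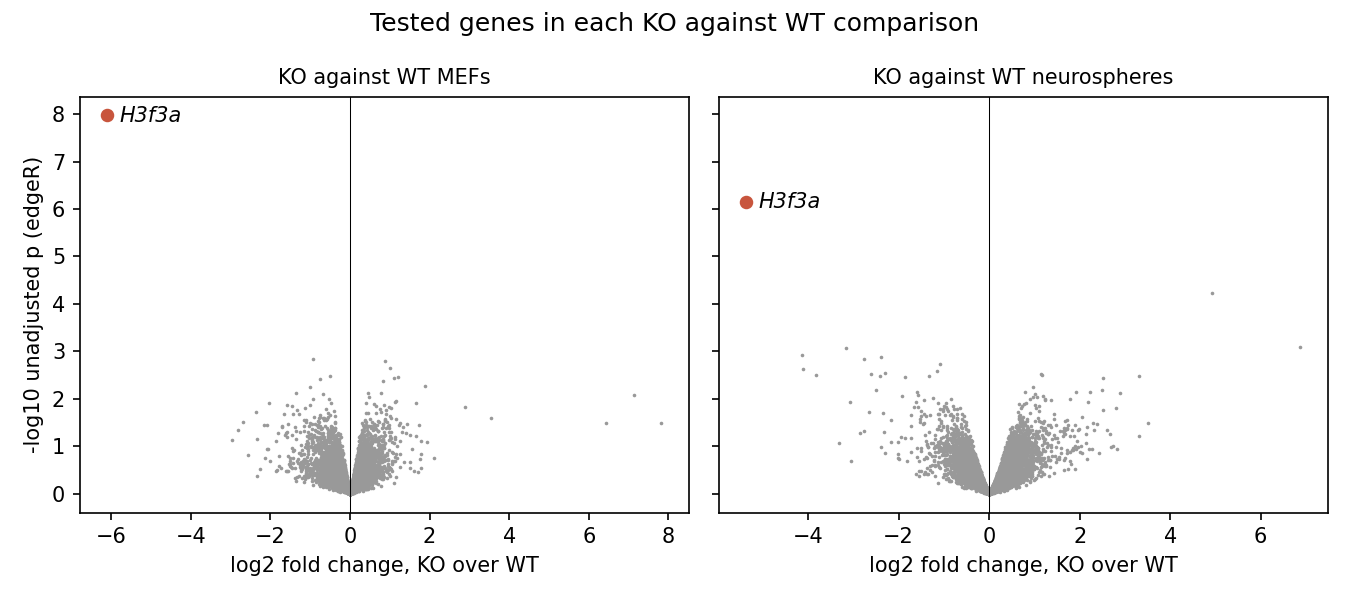
Log2 fold change, KO over WT, against -log10 of the unadjusted edgeR p for every tested gene, 10785 in MEFs (left) and 10624 in neurospheres (right). The marked gene, H3f3a, is the 1 gene that passed in each cell type.

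Histone genes with polyadenylated transcripts, which are read outside S phase, were called lower in KO neurospheres as a list (camera adjusted p = 0.0314; adjusted p = 0.722 with an estimated correlation), with 10 of 14 members negative, a median log2 of -0.08 and a mean of -0.28. Hist1h2bc, an H2B gene, fell from 202 ± 43.5 to 90.7 ± 23.4 CPM (log2 -1.15), called adjusted over the list alone (adjusted p = 0.0365) but not over all genes (adjusted p = 0.999). The linker histone gene Hist1h1c stood at 432 ± 46.9 CPM in WT and 251 ± 69.1 CPM in KO lines (-0.79). Hist3h2a stood at 94.1 ± 10.9 and 60.5 ± 14.4 CPM (-0.63). The call of the list ended without WT neurospheres 3 (adjusted p = 0.161), KO neurospheres 1 (0.0787) or KO neurospheres 2 (0.264). The H2A gene Hist1h2ac, which was not a member of the list, stood at 21.9 ± 5.75 CPM in WT and 4.27 ± 3.37 CPM in KO lines (-2.30). It did not pass over all genes (edgeR adjusted p = 0.999).

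Cholesterol synthesis genes were called lower in KO neurospheres (camera adjusted p = 0.00445; adjusted p = 0.825 with an estimated correlation), with 22 of 24 members negative and a median log2 of -0.36. Acat2 stood at 28.7 ± 3.47 CPM in WT and 16.1 ± 8.90 CPM in KO lines, the reductase gene Dhcr7 at 17.8 ± 5.57 and 10.4 ± 3.98 CPM, and Insig1, a brake on the pathway, at 118 ± 57.7 and 59.1 ± 42.6 CPM. The call ended without WT neurospheres 2 (adjusted p = 0.0850), WT neurospheres 3 (0.276) or KO neurospheres 2 (0.677). The mean log2 deviation of the list was -1.16 in KO neurospheres 2 and from -0.60 to 0.82 in the other 5 lines.

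Nuclear genes of the mitochondrial respiratory chain were called lower in KO neurospheres (camera adjusted p = 0.0337; adjusted p = 0.839 with an estimated correlation), with 32 of 41 members negative and a median of -0.21. Ndufa1, a complex I subunit, stood at 170.9 ± 56.8 CPM in WT and 118.9 ± 20.4 CPM in KO lines. The call ended without KO neurospheres 1 (adjusted p = 0.0787), and the direction turned without WT neurospheres 3 (0.882) or KO neurospheres 2 (0.520). All 9 measured TGF-beta response and contractile genes were negative, with a median of -0.26, among them Id2, an inhibitor of differentiation (1017 ± 336 to 590 ± 213 CPM, log2 -0.78). The list was called lower (camera adjusted p = 0.0337; adjusted p = 0.722 with an estimated correlation). The call ended when any of the 6 lines was left out (adjusted p from 0.0908 to 0.682).

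Neighbours of H3f3a on chromosome 1 were called higher in KO neurospheres (camera adjusted p = 0.0337; adjusted p = 0.722 with an estimated correlation), with 17 of 19 members positive and a median of 0.23. Degs1, an enzyme of ceramide synthesis, stood at 115 ± 20.9 CPM in WT and 154 ± 33.7 CPM in KO lines. The call ended without WT neurospheres 1 (adjusted p = 0.230), WT neurospheres 2 (0.116), KO neurospheres 2 (0.294) or KO neurospheres 3 (0.149), and with both WT neurospheres 2 and KO neurospheres 3 left out (0.282).

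The G2 and M phase genes were called lower in KO neurospheres (camera adjusted p = 0.0314; adjusted p = 0.839 with an estimated correlation), although the median of their fitted log2 values was 0.08 and the mean 0.13. Proliferation genes differed widely between lines of both genotypes. Mki67, a marker of cycling cells, had 53.7, 154.9 and 174.3 CPM in WT neurospheres 1 to 3 and 76.5, 6.23 and 298.4 CPM in KO neurospheres 1 to 3. Top2a, a topoisomerase gene, had 3.11 CPM in KO neurospheres 2 and 64.1 to 693 CPM in the other 5 lines. These genes were chosen after their values were seen. Without KO neurospheres 2 the list turned to higher in KO lines (camera adjusted p = 0.0165), and its call ended without WT neurospheres 2 (0.167), WT neurospheres 3 (0.854) or KO neurospheres 1 (0.147). S phase genes had positive values in 27 of 30 members (median 0.35, camera adjusted p = 0.766). They were called higher without KO neurospheres 2 (camera adjusted p = 0.00195), but lower without KO neurospheres 3 (1.77e-06) and with both WT neurospheres 2 and KO neurospheres 3 left out (0.00221).

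In all, camera called 6 of 25 tested lists in neurospheres, 1 higher and 5 lower in KO lines, and fry called 0, with a smallest adjusted p of 0.915 in either direction. Other splits of the neurosphere lines into groups of the same sizes gave a median of 6 lists by camera, so this count does not set the genotypes apart. The count of lists was 2 without WT neurospheres 3, 3 without KO neurospheres 1 and 3 without KO neurospheres 2. Immediate early genes, with Fos at 121 ± 43.0 CPM in WT and 255 ± 108 CPM in KO lines, had a camera adjusted p of 0.0780. They were called higher with replicate number as a block (0.0264), without WT neurospheres 2 (0.0356) and with both WT neurospheres 2 and KO neurospheres 3 left out (0.0321). Neural stem and progenitor markers had 13 of 18 members with positive values (median 0.05, camera adjusted p = 0.287; called higher without WT neurospheres 1, 0.00706), astrocyte markers 8 of 13 (median 0.02, 0.209) and neuron markers 5 of 12 (median -0.48, 0.643). H3 chaperones had 10 of 16 (median 0.06, 0.951, with the test's direction downward), and H3 lysine methylation enzymes 14 of 28 (median -0.01, 0.354). The endothelial adhesion gene Pecam1 fell from 9.29 ± 3.62 to 3.07 ± 0.940 CPM (log2 -1.56), called adjusted over the list alone (adjusted p = 0.0294), in a list with 2 measured members, but not over all genes. No further list member passed over all genes or adjusted over the list alone, apart from H3f3a and Hist1h2bc.

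To ask whether the genotype acted differently in the 2 cell types, the KO effects were tested against each other. By the edgeR quasi-likelihood test the KO effect on H3f3a differed by a log2 of 0.71 between neurospheres and MEFs (SE 0.48) and that on H3f3b by 0.18 (SE 0.33), each with an adjusted p of 1.00. The genes nearest to the threshold were Fras1 (log2 difference of KO effects -5.11), Gnai1 (-1.86), Tusc1 (-3.75) and the caveola component Cavin2 (2.59), followed by Fbxl7 (-2.72), Msl3l2 (5.77), the growth hormone receptor gene Ghr (-2.44) and the histone deacetylase gene Hdac7 (-0.78), each with an adjusted p of 1.00. By edgeR 0 of 12113 genes passed, with 366 at an unadjusted p under 0.05 and 606 expected by chance. This count, too, moved with the lines, from 287 (without KO neurospheres 2) to 777 (without KO neurospheres 3). DESeq2 called 3 genes, Pcdha12, Fras1 (adjusted p = 0.00395) and Gnai1 (0.0469), with 443 at an unadjusted p under 0.05. Across 9460 genes without H3f3a, which are not independent replicates, the KO effects in MEFs and neurospheres had a Pearson r of 0.0075 and a Spearman rho of -0.0041, and 49.5% of genes had the same sign in both.

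The WT lines show what each cell type expressed. Neurospheres expressed neural and glial genes that MEFs lacked: Bcan, a brain matrix proteoglycan, stood at 759.9 ± 9.99 CPM in WT neurospheres and at 0 counts in all WT MEFs, at least 2166-fold higher (floor of 3 counts over the group). The glial transcription factor gene Olig2 (569 ± 145 CPM, at least 1622-fold), the glutamate receptor gene Gria2 (288 ± 180 CPM, at least 821-fold) and Tmem229a (281 ± 103 CPM, at least 802-fold) were also at 0 counts in WT MEFs. MEFs expressed smooth muscle actin Acta2 at 2258 ± 854 CPM, with 0 counts in WT neurospheres (at least 5592-fold lower), and Aspn, a matrix proteoglycan, at 376 ± 130 CPM (at least 931-fold lower). Thbs1 (3273 ± 971 to 0.250 ± 0.217 CPM), Ccn2 (2010 ± 971 to 0.120 ± 0.208 CPM) and the collagen cross-linking enzyme Lox (2522 ± 995 to 0.259 ± 0.449 CPM) were lower in neurospheres as well. By edgeR 4614 of 11080 genes differed, 2304 higher and 2310 lower in neurospheres, and the lines did not overlap in 6317 genes (57.0%), against 10% by chance.

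H3f3a was higher in WT neurospheres than in WT MEFs, 2197 ± 234 against 1045 ± 328 CPM when scaled together (log2 1.07, SE 0.27, edgeR adjusted p = 0.0148; exact permutation p = 0.1, the smallest possible). H3f3b stood at 1965 ± 378 and 1527 ± 314 CPM (log2 0.36, SE 0.25, adjusted p = 0.268). The H3f3a call ended without WT MEFs 1 (adjusted p = 0.0700), WT MEFs 3 (0.0692) or WT neurospheres 1 (0.0546).

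Of 18 neural stem and progenitor markers, 16 were higher in neurospheres and 1 in MEFs (17 called adjusted over the list alone). The fatty acid binding protein gene Fabp7 went from 5.64 ± 1.29 CPM in MEFs to 2411 ± 808 CPM in neurospheres (log2 8.72) and Ptprz1 from 64.7 ± 11.5 to 3831 ± 867 CPM (5.89). Astrocyte markers were higher in 7 and lower in 1 of 11 (8 called adjusted over the list alone), with Sparcl1 at 4.74 ± 1.14 and 6692 ± 3323 CPM. Oligodendrocyte lineage markers were higher in 5 and lower in 2 of 8 (7 adjusted over the list alone), and neuron markers in 5 and 2 of 11 (7 adjusted over the list alone). Of 15 fibroblast markers, 14 were higher in MEFs (14 adjusted over the list alone), with S100a4 at 738.5 ± 312 CPM in MEFs and 1.80 ± 1.38 CPM in neurospheres. Of 48 collagens and matrix genes 46 were higher in MEFs (46 adjusted over the list alone), with fibronectin, Fn1, at 3298 ± 616 and 30.4 ± 10.6 CPM. All 6 measured markers of macrophages, microglia and blood were higher in MEFs (6 adjusted over the list alone), among them Lyz2 at 58.6 ± 34.9 and 1.39 ± 0.458 CPM.

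The growth and protein synthesis machinery differed too. MEFs had higher levels of 27 of 42 G2 and M phase genes (34 called adjusted over the list alone), 19 of 35 S phase genes (24), 49 of 74 ribosomal protein genes (64) and 19 of 26 genes of the unfolded protein and amino acid stress response (22), where the numbers in brackets are those adjusted over the list alone. Examples are the replication helicase gene Mcm4 (195 ± 21.8 CPM in MEFs, 39.3 ± 15.5 CPM in neurospheres), the ribosomal protein gene Rps2 (646 ± 195 and 162 ± 17.7 CPM) and the chaperone gene Hspa5 (1626 ± 303 and 248 ± 67.3 CPM). Neurospheres had higher levels of 12 of 13 mitochondrially encoded genes (13 adjusted over the list alone), with mt-Co1 at 1848 ± 230 CPM in MEFs and 5476 ± 416 CPM in neurospheres.

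Lines of 1 genotype differed among themselves by body region genes. In MEFs the first principal component held 53.01% of the variance and set WT MEFs 2 (score 72.6) and KO MEFs 3 (67.3) apart from the other 6 lines (-29.1 to -18.7). Of 28 Hox genes, which mark position along the body and limb, 21 were among the 1078 genes with the largest loadings, with 2.80 expected. Other developmental transcription factors had 23 of 42 there (4.20 expected), and collagens and matrix genes 16 of 50 (5.00 expected). Hoxd13, a Hox gene of the digits, had 248 CPM in WT MEFs 2 and 208 CPM in KO MEFs 3, against 4.09 to 32.0 CPM in the other 6 lines. Tbx4, a hindlimb gene, had 82.5 and 67.0 CPM against at most 6.64 CPM. The Hox gene Hoxc10 went the other way, with 1.43 and 2.89 CPM against 15.2 to 31.0 CPM. Tbx5 was high in KO MEFs 3 (35.7 CPM) but not in WT MEFs 2 (6.07 CPM). Ncam1, a cell adhesion gene, had 133.6 and 201 CPM against 1287 to 1458 CPM. In neurospheres the first component held 41.7% of the variance and ran from KO neurospheres 2 (63.6) to KO neurospheres 3 (-44.3), and the 1062 genes with its largest loadings held 39 of 42 G2 and M phase genes (4.20 expected) and 17 of 24 cholesterol synthesis genes (2.40 expected). Hoxa2, a hindbrain gene, had 19.7 CPM in WT neurospheres 2 and 18.0 CPM in KO neurospheres 3 and 0 counts in the other 4 lines. Hoxa5 was not confined to these lines, with 454.2 and 129.9 CPM there, 66.6 CPM in KO neurospheres 2, 10.8 CPM in KO neurospheres 1 and at most 0.384 CPM in WT neurospheres 1 and 3. Otx2, a gene of the forebrain and midbrain, had 0 and 0.367 CPM in these 2 lines and 21.6 to 62.2 CPM in the other 4. The genes named by line in this paragraph were chosen after their values were seen.

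**Figure D3:**
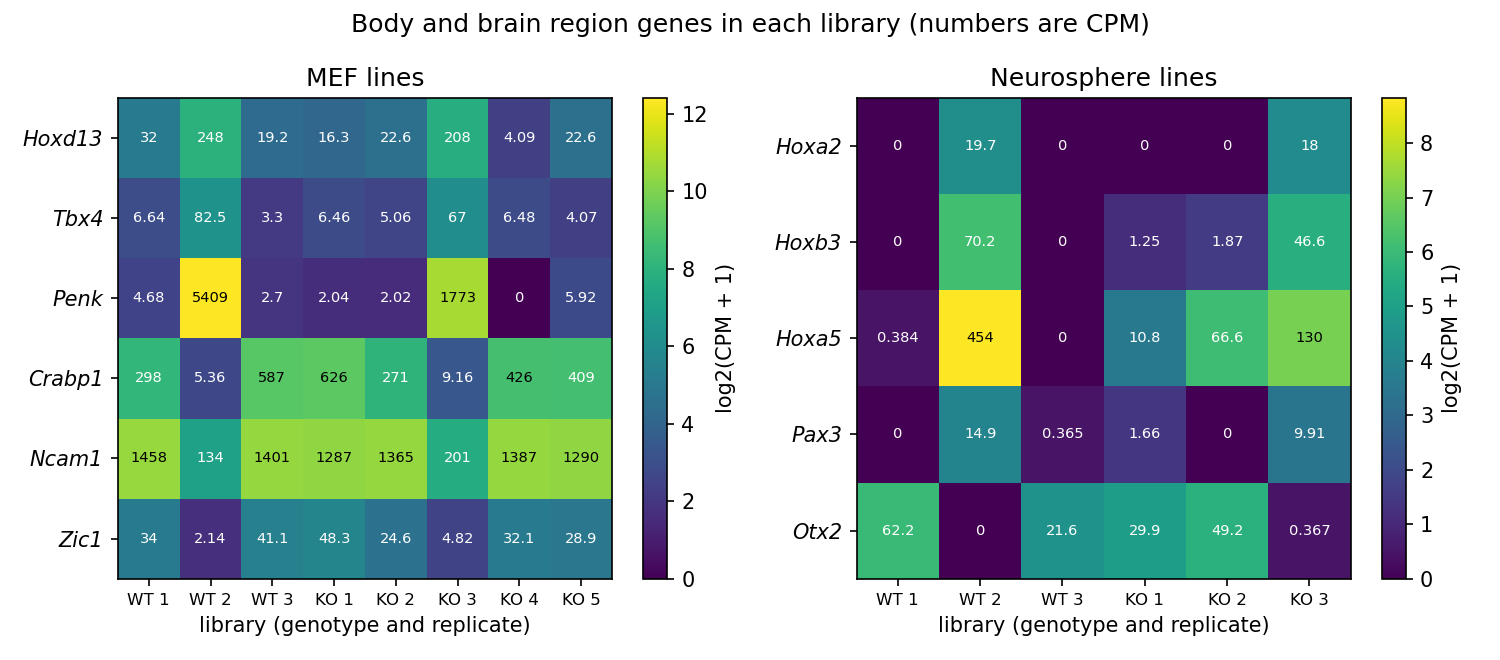
Genes of body and brain regions in each of the 8 MEF lines (left) and 6 neurosphere lines (right), as a heat map of log2(CPM + 1) with the CPM printed in each field. WT MEFs 2 and KO MEFs 3 are the 2 lines with Hoxd13 above 200 CPM, and WT neurospheres 2 and KO neurospheres 3 the 2 neurosphere lines with Hoxa2 counts.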

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

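The tests of other splits of the lines were planned before the data were examined, and the tests of where lines came from, of carried-over cells and of the counts left on H3f3a were chosen after the values had been seen.

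Of 28 tests for a line far from the other lines of its group, all among the 5 KO MEF lines, 5 found KO MEFs 3 outside the others. KO MEFs 3 had a first component score of 67.3, against -29.1 to -18.7 in the other KO lines. Chance flags about 1 in 20 groups, so that some of 28 tests would be met without a cause. That rate holds for none of these 5 values: the first component is by construction the direction of largest spread, and the other 4 are of genes picked after their values were seen because they set this line and WT MEFs 2 apart. The 5 values only describe the pattern. KO MEFs 3 had 207.8 CPM of the digit gene Hoxd13 (others 4.09 to 22.6), 67.0 CPM of the hindlimb gene Tbx4 (4.07 to 6.48) and 1773 CPM of the opioid peptide gene Penk (0 to 5.92). Ncam1 stood at 201.1 CPM, against 1287 to 1387 CPM in the other KO lines.

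WT MEFs 2 and KO MEFs 3 stand apart from the other 6 MEF lines in the same way. Library size argues against itself as the source, since WT MEFs 2 had 2743607 counts, inside the 2655360 to 3296178 of the other 6. Macrophages carried along are argued against by their markers, whose mean log2 deviation was 1.40 in WT MEFs 2 but -1.22 in KO MEFs 3. A candidate explanation, as a hypothesis, is the part of the body the lines grew from: of 2 lists of 10 genes written after the pattern was seen, the limb genes summed to 290.3 CPM in the lower of these 2 lines and at most 178.8 CPM in the others, and the trunk genes to 52.6 CPM in the higher of them and at least 119.1 CPM in the others. The limb list is not specific to limb, since it summed to 219.2 to 330.1 CPM in the 6 neurosphere lines, which come from heads, so these sums leave the body part open. The labels do not say which tissue entered each line, and genotype was not weighed, since each genotype holds 1 of these lines.

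WT neurospheres 2 and KO neurospheres 3 had Hoxa2 transcripts, which the other 4 neurosphere lines lacked. Not every Hox gene followed this pattern: Hoxa5 had 129.9 CPM in KO neurospheres 3 but also 66.6 CPM in KO neurospheres 2 and 10.8 CPM in KO neurospheres 1. Fibroblasts carried along are argued against, since the highest Col1a1 level in these lines was 0.481 CPM, against at least 4971 CPM in MEFs, and since their Hoxa2 would need 10.5 times the highest level of any MEF line. The brain region the lines came from may be the source, but sums over gene lists cannot tell: genes of hindbrain and spinal cord summed to 37.1 CPM in the lower of these lines, inside the 23.4 to 41.1 CPM of the other 4, and forebrain genes to 35.2 CPM in the higher, below the 45.7 to 52.8 CPM of the others.

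KO lines kept 21 to 143 counts on H3f3a. Whether reads were shared with another gene stays open. The estimates lay within 0.009 of whole numbers, but whole values were usual: 16.2% of values of expressed genes in KO libraries lay more than 0.05 from one. A fixed share of H3f3b reads is argued against, since the H3f3a counts were 1.02% of those of H3f3b in KO MEFs and 2.42% in KO neurospheres (exact two-sided permutation p = 0.0179). Reads or cells of the WT MEF lines in equal shares are argued against by 0 counts of Ddx3y and Eif2s3y in the 3 KO MEF lines without Y expression, where 10.05 were expected (exact Poisson p = 4.34e-05). This p covers counting error only, and PCR copies, which cannot be told apart here, would make it too small. WT MEFs 2 alone as the source is argued against for KO MEFs 1, 2, 4 and 5, since it had 5409 CPM of Penk beside 1417 CPM of H3f3a, while these lines had at most 5.92 CPM of Penk beside 7.16 to 18.6 CPM of H3f3a. WT MEFs 3 alone as the source, and transcripts that pass the cassette, were not tested.

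Other splits of the lines bear on the counts. For genes in MEFs 6 of 56 splits gave at least the 1 gene of the real split, so chance is not excluded for this count. The count does not weigh which gene passed: in the real split it was the targeted H3f3a (exact two-sided permutation p = 0.0179). The highest other split gave 333 genes. That split put WT MEFs 2, KO MEFs 2 and KO MEFs 3 against the other 5 lines, which points to a structure of the samples. For MEF lists 52 of 56 splits gave at least the 2 lists of the real split, up to 11, so chance is not excluded. The median of the other splits was 5 lists, and all 55 of them gave at least 1. In neurospheres all 9 other splits gave at least 1 list, with a median of 6, so the count of lists does not set the genotypes apart. For a test of chance the 10 splits are too few to decide: 2 gave at least 1 gene, with 1 as the highest other, and 6 gave at least the real 6 lists, with 10 as the highest. The same holds for WT neurospheres against WT MEFs, where 1 of 10 splits, the real one, gave 4614 genes and the highest other 0. For the interaction the real count is 0, which all 100 drawn splits had to reach, so these splits say nothing about chance. The highest of them gave 383 genes.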

How the results depend on the processing

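Fits without the pair of lines in each cell type that differed in region genes were chosen after the data were seen. The same holds for fits with a sex covariate and with the first residual component, while the other alternatives were planned. The call of H3f3a in MEFs held under the other full-data alternatives that keep the gene and without the lines that stand apart (log2 -6.10 to -5.66) and was lost with the replicate number as a block (log2 -5.81, adjusted p = 0.0796), which also gave 0 genes. The labels state no pairing by these numbers. After removing group means, WT MEFs 1 to 3 correlated with the KO MEFs of their number at 0.029, -0.261 and -0.588. For WT neurospheres 1 to 3 these values were 0.126, -0.108 and 0.225. They cannot show whether lines were paired, since other differences between lines, such as those in region genes, enter them too. With genes within 10 Mb of H3f3a left out 0 genes passed in either cell type, since H3f3a is among them. Without WT MEFs 2 and KO MEFs 3, 3 genes passed in MEFs, and without WT neurospheres 2 and KO neurospheres 3, 3 passed in neurospheres. The neurosphere pair was picked by region genes and is not set apart by the first component. There WT neurospheres 3 scored -29.1, between WT neurospheres 2 (-24.8) and KO neurospheres 3 (-44.3). In neurospheres DESeq2 gave 5 genes and no filter 2; H3f3a kept its call under the same alternatives and the block (-5.47 to -5.06), but lost it without WT neurospheres 2 (adjusted p = 0.0801) or KO neurospheres 1 (0.202). For the interaction DESeq2 gave 3 genes. For other counts and values that changed under an alternative the cause was not tested.

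Leaving out 1 line at a time gave 1 to 1 genes and an H3f3a log2 of -6.22 to -5.79 in MEFs, 0 to 2 genes and -5.66 to -5.05 in neurospheres, 0 to 0 genes for the interaction and 3414 to 5206 genes between the WT cell types, where the other alternatives gave 3915 to 5151. H3f3b in MEFs turned positive with the block (0.15) and without WT MEFs 2 (0.16), KO MEFs 1 (0.01), KO MEFs 4 (0.07) or KO MEFs 5 (0.03), within a range of -0.20 to 0.16. The named genes other than H3f3a made 38 pairs of a gene and a comparison, since some genes were named in more than 1 comparison. Of their 655 values 11 differed in call or direction, and the 5 that turned direction are those of H3f3b in MEFs. This count leaves out genes named only as list members or after their values were seen. Some of those turned direction too, such as Ddx3y in MEFs in 2 of 17 settings.

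MEF lists numbered 5 with the block, 0 with an estimated correlation, 0 by fry, 4 without the lines that stand apart and 3 to 6 leaving out lines. Neurosphere lists numbered 7 with the block, 0 with an estimated correlation, 0 by fry and 2 to 7 leaving out lines. Leaving out lines, the adjusted p of the G2 and M phase list ran from 2.46e-14 (without KO neurospheres 3) to 0.854 (without WT neurospheres 3), and it turned direction without KO neurospheres 2 (0.0165). That of the respiratory chain list ran from 3.42e-05 (without KO neurospheres 3) to 0.882 (without WT neurospheres 3), where it turned direction, as it did without KO neurospheres 2 (0.520). These values rest on the preset correlation of 0.01, while the estimated one was 0.905 for the G2 and M phase list and 0.711 for the respiratory chain list.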

Other observations

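Other gene groups also differed between the WT cell types. MEFs had higher levels of 12 of 16 senescence and secreted inflammatory genes (13 called adjusted over the list alone), among them the chemokine gene Ccl7 (89.1 ± 27.5 CPM in MEFs, 0.130 ± 0.225 CPM in neurospheres). They also had higher levels of 19 of 24 TGF-beta response and contractile genes (21 adjusted over the list alone), with the myosin light chain gene Myl9 at 144.5 ± 29.3 and 0.819 ± 0.123 CPM, and of 11 of 20 interferon-stimulated genes (11 adjusted over the list alone). Of 26 hypoxia and glycolysis genes 7 were higher in MEFs and 2 in neurospheres (9 adjusted over the list alone). Of 24 cholesterol synthesis genes 2 were higher in MEFs and 1 in neurospheres (0 adjusted over the list alone). Of 41 nuclear respiratory chain genes 14 were higher in neurospheres and 0 in MEFs by edgeR (13 adjusted over the list alone).

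Chromatin and imprinted genes went both ways. Of 17 histone H3 chaperones 4 were higher in neurospheres and 6 in MEFs (10 adjusted over the list alone), with Asf1b, which hands new histones to the replication machinery, at 34.7 ± 7.54 CPM in MEFs and 3.51 ± 2.72 CPM in neurospheres. Of 29 H3 lysine methylation enzymes 8 were higher in neurospheres and 2 in MEFs (9 adjusted over the list alone), with Nsd2 at 100.1 ± 7.84 and 273 ± 35.4 CPM. Of 14 histone variants with polyadenylated transcripts 6 were higher in neurospheres and 2 in MEFs (12 adjusted over the list alone), with Hist1h1c at 119 ± 26.1 and 432 ± 47.1 CPM. Of 20 imprinted genes 6 were higher in neurospheres, such as Nnat (8.38 ± 6.999 and 705.9 ± 341 CPM), and 7 in MEFs, such as Dlk1 (172 ± 15.3 and 4.69 ± 3.19 CPM), with 14 adjusted over the list alone.

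Y chromosome transcripts differed between lines of both genotypes. Ddx3y had 206 CPM in WT MEFs 1, 214 in KO MEFs 1, 211 in KO MEFs 5, 134.3 in WT neurospheres 1 and 134.0 in KO neurospheres 3, and at most 1.25 CPM in the other 9 lines.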
